A study of Homo sapiens with 8 samples.

How the data were processed

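The series profiled binding of the transcription factor SOX9 by chromatin immunoprecipitation and sequencing (ChIP-seq) in hES-RPE cells, which are retinal pigment epithelium cells differentiated from the established human embryonic stem cell line Hes1. Per the labels' protocols, sonicated chromatin was immunoprecipitated with a rabbit antibody against SOX9, and libraries were made with an Illumina sample preparation kit. The labels list 8 libraries. Of these, 6 are SOX9 immunoprecipitates carrying 3 replicate numbers, each with an s1 and an s2 library, and 2 are input libraries named s1 and s2. The labels do not say what s1 and s2 stand for, nor whether replicate numbers mark separate cultures.

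The only processed file used here is a merged peak list with 6 columns and no header, which the labels of all 8 libraries name. Per the submitters' processing notes, Bowtie2 and MACS2 were used and the build was hg19. Versions, the role of the input, the peak threshold and the way the replicates were merged are not given in the sources used here. For each peak the authors deposited a chromosome, a start, an end, a name and a score. The deposited score ran from 3.27 to 36.23 with no unit given, so it was used only within the list: to describe, rank and select peaks, in correlations with width, and in an examination of how its values are spaced. No value per library was used, so the spread between replicates, the depth of each library and the enrichment over input are not analysed here, and no comparison of immunoprecipitate with input was made. All p-values below describe the arrangement of peaks within this list and do not measure variation between cultures.

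Starts were converted to 1-based positions. The gene table used is of the GRCh38 assembly, and the submitters' processing notes name hg19, so no coordinate of that table was used to place the peaks. In that table's coordinates, 14 peaks on 6 chromosomes lay past the last gene of their chromosome, which alone does not decide the build. The table served otherwise only to count protein-coding genes per chromosome, which needs no position. Because neither sequence nor annotation of hg19 was used, the comparisons planned on distance to transcription start sites, annotation class, SOX and other motifs, motif spacing, score against motif, and 16 gene lists (among them visual cycle, melanin, eye transcription factor, angiogenic and cartilage genes) were not run. No peak was assigned to a gene, and the planned rule for naming genes therefore names regions: the 10 peaks with the highest scores. Other regions named were chosen after their values were seen.

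Peaks per chromosome were compared with the share of 19970 protein-coding genes on chromosomes 1 to 22 and X by 2-sided exact binomial tests with Benjamini-Hochberg adjustment over 23 chromosomes and exact (Clopper-Pearson) 95% intervals, which cover counting error only. The plan had foreseen a comparison with sequence length from a genome and no test without it, so the gene share was chosen after the list was seen. Scores were compared between chromosomes by permutation of score ranks (100000 permutations, 2-sided). Distances between midpoints of neighbouring peaks were compared with 1000 random placements of the peaks, uniform between the first and last peak of each chromosome, or with each peak moved by up to 1 Mb or up to 100 kb. Sequence gaps could not be left out of the random placements. The spacing and score comparisons and the random moves were also chosen after the list was seen. Score and width were compared by Pearson and Spearman correlation across peaks with 100000 permutations. Peaks are not independent replicates.

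Of the alternatives run, those fixed before the data were examined were 2 for the peaks per chromosome: the peaks scoring above the median (571 peaks) and the merging of peaks less than 1 kb apart (1054 peaks). The same settings for spacing, score and width were added after the data were seen. Further alternatives, also added later, took the expectation per chromosome from the span of the peaks, left out ZNF-named genes, or left out single chromosomes. The tests were checked on simulated lists of 1146 peaks. To plant an excess on chromosome 19, its share was multiplied by 1.5 and all shares were then rescaled. The planted ratio was thus slightly below 1.5. This excess was called in 75 of 100 lists, and 5 of 100 unchanged lists gave any call. With 60 planted neighbouring pairs, 100 of 100 lists were called, against 1 of 100 unchanged lists. This check used uniform placement only, with fewer placements than the test, and drew the unchanged lists uniformly too. The planted number lies far above the uniform random mean of 0.75. Smaller excesses, uneven peak density and the random moves were therefore not checked. A score shift of 2 planted on chromosome 19 was called in 20 of 20 lists, against 0 of 20 unchanged lists. That shift is larger than the difference between the observed medians (7.29 on chromosome 19, 6.4 elsewhere), so a difference of the observed size was not checked. For the chromosome test the simulated peaks were placed independently, so its rates do not cover a list with many close pairs. Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.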

Results

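SOX9 is an HMG-box transcription factor with known roles in cartilage, testis and neural crest development that is also present in the retinal pigment epithelium, the pigmented layer that supports the photoreceptors. The series asked where SOX9 binds the genome of hES-RPE cells, and its 8 libraries, 6 SOX9 immunoprecipitates and 2 inputs, are represented by a single merged list of 1146 peaks in hg19 coordinates. The list holds neither read counts nor values per replicate, so the sequencing depth behind each peak is unknown and the peaks carry no replicate error.

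SOX9 peaks were short and spread over chromosomes 1 to 22 and X. The 1146 peaks covered 201858 bp in total, none overlapped its neighbour and none lay on unplaced or alternate sequences. The median width was 152 bp (quartiles 122 and 199 bp), and 42 peaks had the smallest width in the list, 99 bp. Peaks wider than 500 bp numbered 12. The median score was 6.49 (quartiles 5.47 and 8.21), and 148 peaks (12.9%) scored above 10.

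The peak with the highest score and the widest peak were the same region, on chromosome 11 from 5246105 to 5247378. Its score of 36.23 stood above the next score of 27.64, and its width of 1274 bp stood above the next width of 686 bp. A second peak with a score of 15.26 lay beside it, from 5247690 to 5247863, with midpoints 1035 bp apart. Because this region stands far apart from the rest of the list, its score and width cannot be read as SOX9 binding without a check for carried-over plasmid or vector DNA, which was not made here. The next highest scores belonged to chromosome 19 from 6424876 to 6425204 (27.64), chromosome 15 from 98503587 to 98503929 (26.35), chromosome 9 from 131843076 to 131843453 (25.77) and chromosome 2 from 10262676 to 10262885 (25.5). The remaining peaks among the 10 highest were on chromosome X from 47415481 to 47415727 (24.08), chromosome 16 from 3053906 to 3054202 (23.7), chromosome 5 from 43313733 to 43314004 (21.69), chromosome 10 from 99052337 to 99052563 (21.66) and chromosome 3 from 148804282 to 148804503 (20.92). These 10 regions lay on 10 different chromosomes, and the 9 below the first were 210 to 378 bp wide. Genes at these positions are not reported because no hg19 annotation was used here.

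Higher-scoring peaks were wider. Median width was 128 bp in the 287 peaks with the lowest scores and 191 bp in the 287 peaks with the highest scores, with 130.5 bp and 154 bp in the groups of 286 between them. Across peaks, Spearman's rho was 0.47 and Pearson's r was 0.40, each with a permutation p of 1e-05, the smallest that 100000 permutations can give. Without the 2 peaks farthest from the median score, r was 0.33 and rho was 0.47.

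**Figure D1:**
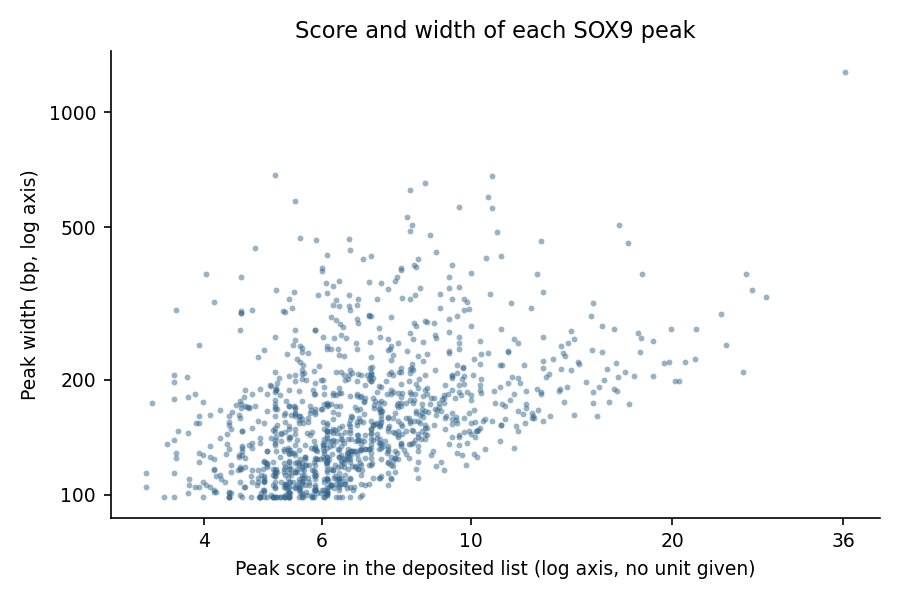
Width in bp of each of the 1146 SOX9 peaks (vertical, log axis) against its score in the deposited list (horizontal, log axis, no unit given), 1 point per peak. The single point at a score of 36.23 and a width of 1274 bp is the region on chromosome 11, which was not checked for carried-over plasmid or vector DNA.

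Chromosome 19, a gene-dense chromosome, carried more SOX9 peaks than any other chromosome. It held 129 peaks, 11.3% of the list (95% interval 9.48 to 13.2%), where its 1451 protein-coding genes predicted 83.3 peaks, a ratio of 1.55 (interval 1.31 to 1.82, adjusted p = 2.67e-05, exact binomial test). This came to 8.89 peaks per 100 protein-coding genes on chromosome 19, against 5.49 over the other chromosomes together. Per 10 Mb between the first and last peak, chromosome 19 held 22.2 peaks and the other chromosomes together held 3.65. Chromosome X held fewer peaks than its genes predicted, 23 against 48.7 (ratio 0.473, interval 0.301 to 0.706, adjusted p = 0.00058, exact binomial test). Chromosome 13 held 35 against 19.4 (ratio 1.80, interval 1.26 to 2.49, adjusted p = 0.00898, exact binomial test). The other 20 chromosomes did not pass the adjusted test, and their ratios ran from 0.656 on chromosome 21 to 1.61 on chromosome 18. Among peaks scoring above the median only chromosome 19 passed (ratio 1.88), with 0.577 on chromosome X and 1.66 on chromosome 13. Chromosome 13 also missed the threshold after neighbouring peaks were merged (ratio 1.68, adjusted p = 0.0608, exact binomial test). Its ratio was 0.955 when the expectation came from the span of the peaks.

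**Figure D2:**
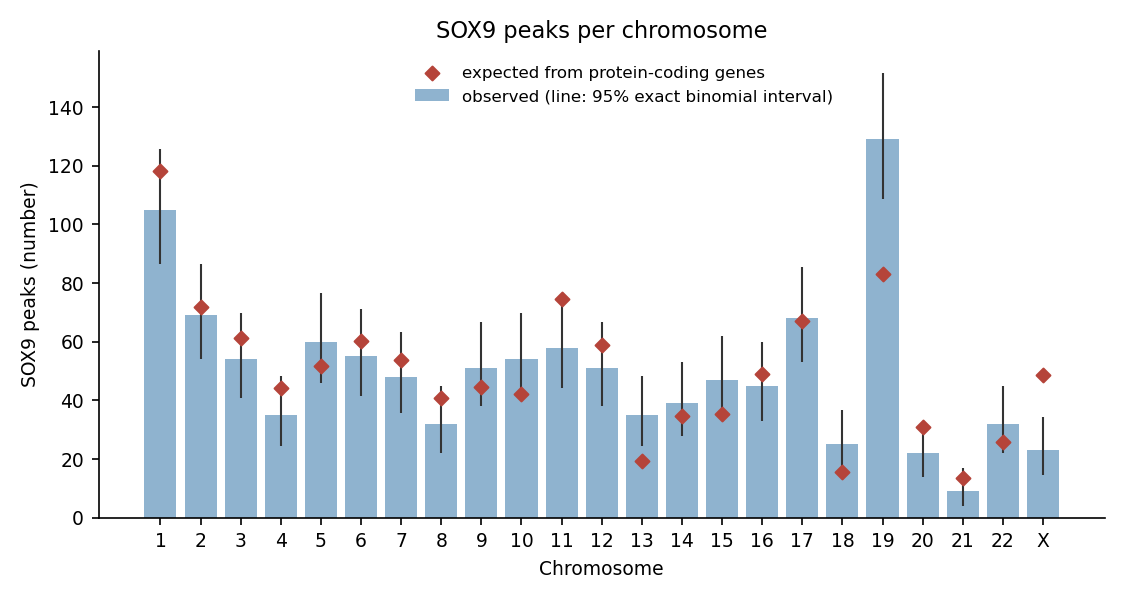
Number of SOX9 peaks (vertical) on each chromosome (horizontal). Bars show the observed number, with lines for the 95% exact binomial interval, and diamonds show the number expected from the chromosome's share of protein-coding genes. The bar of chromosome 19 reaches 129 with a diamond at 83.3, and that of chromosome X reaches 23 with a diamond at 48.7.

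Peaks on chromosome 19 also scored higher. Their median score was 7.29, against 6.4 for peaks on the other chromosomes, and their mean score percentile was 58.1 where 50 marks no difference (adjusted p = 0.017 over 23 chromosomes, permutation test). No other chromosome passed this test, and the next lowest adjusted p was 0.234 for chromosome 3, where the median score was 5.84. After merging of peaks less than 1 kb apart, the percentile of chromosome 19 was 57.3 and the call was lost (adjusted p = 0.0623, permutation test).

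Peaks on chromosome 19 were spread over its length. Successive 10 Mb parts from position 1 held 29, 30, 16, 19, 23 and 12 peaks. The longest stretch without a peak, 7.90 Mb, lay between a peak ending at 23945789 and a peak starting at 31841781. Whether sequence gaps lie in this stretch was not checked, so it cannot be read as a lack of binding. Of the 14 windows of 1 Mb in the genome with 5 or more peaks, 8 were on chromosome 19. The densest lay between 46000001 and 47000000 with 8 peaks, the highest scoring 8.37, and the next between 20000001 and 21000000 with 7 peaks, the highest scoring 9.76. Outside chromosome 19, windows with 5 peaks included 49000001 to 50000000 on chromosome 12 and 8000001 to 9000000, 74000001 to 75000000 and 79000001 to 80000000 on chromosome 17.

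**Figure D3:**
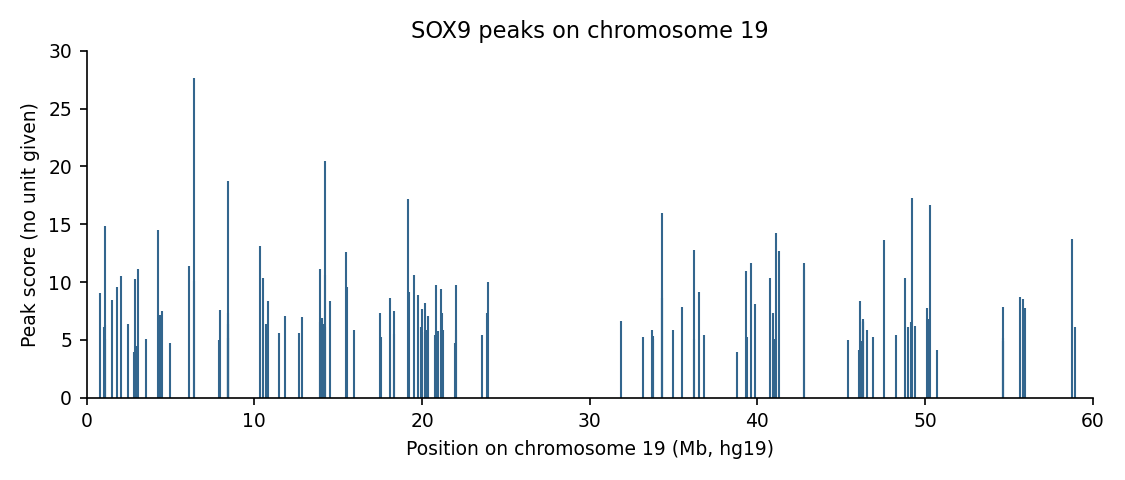
Positions of the 129 SOX9 peaks on chromosome 19 (horizontal, Mb in hg19), each drawn as a line whose height is its score in the deposited list (vertical, no unit given). Peaks stand on both sides of a 7.90 Mb stretch without any, and the tallest line is the peak that scored 27.64.

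Many SOX9 peaks lay next to another peak. In 84 of 1123 neighbouring pairs the midpoints were at most 1 kb apart, and 61 of these were within 500 bp. These pairs held 158 peaks (13.8%) on 21 chromosomes, while the median distance between neighbours was 988 kb. Uniform random placement gave 0.75 ± 0.866 such pairs (mean and SD of 1000 placements), and at most 4. The adjusted p was 0.00266 over 12 comparisons (random placement test). The unadjusted p was 0.002, the smallest that 1000 placements can give. Moving each peak by up to 100 kb, which keeps the density only at scales well above 100 kb, gave 2.54 ± 1.55 pairs and at most 8. Distances of 1 to 10 kb were seen 27 times, against a mean of 6.22 and at most 16 under uniform placement. Moves of up to 100 kb gave 21.9 ± 4.54 pairs at this distance, and the difference from 27 did not pass the test (adjusted p = 0.318, permutation of peak positions). Moves of up to 1 Mb gave 9.83 ± 3.22 such pairs (adjusted p = 0.00266, permutation of peak positions). The moves spread close pairs over wider distances and so raise the random counts there. At 10 to 100 kb, 103 pairs were seen, against 161 ± 7.84 with moves of up to 100 kb (adjusted p = 0.00266, permutation of peak positions).

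Runs of 3 neighbouring peaks, each within 1 kb of the next, occurred at 10 places. The run with the highest score lay on chromosome 19 from 34286366 to 34287490, with scores of 8.62 to 15.99, and the next on chromosome 9 from 131939779 to 131940711, with scores of 7.3 to 8.98. Paired peaks were wider than the other 988 peaks, with median widths of 167 and 150 bp (adjusted p = 0.00994 over 2 comparisons, permutation test). Their median scores were 6.36 and 6.55, a difference that did not pass the test (adjusted p = 0.0588, permutation test).

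**Figure D4:**
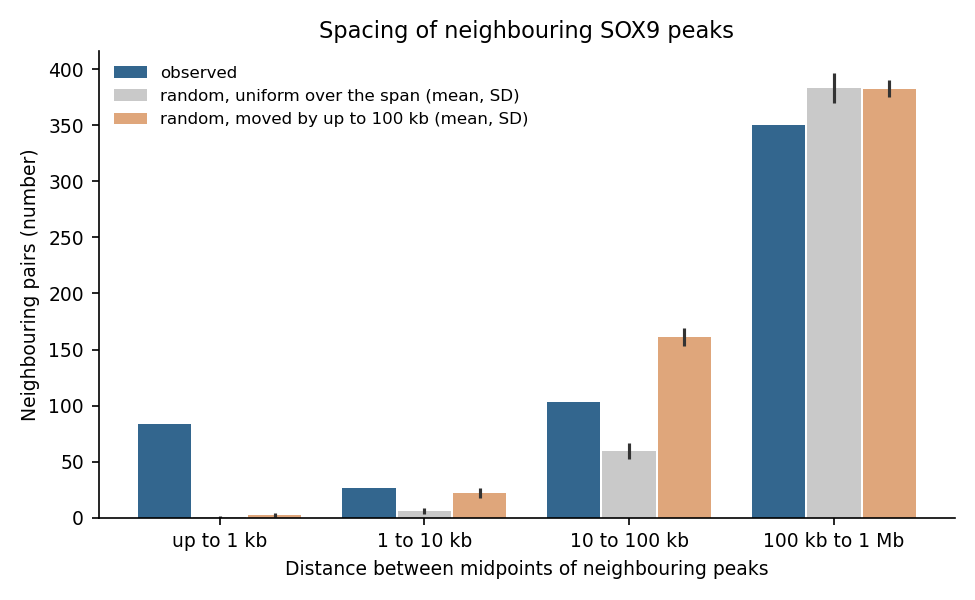
Number of neighbouring peak pairs (vertical) by distance between their midpoints (horizontal). Dark bars are the observed list, and the light bars are means of 1000 random lists with lines for the SD, with peaks placed uniformly between the first and last peak of each chromosome or moved by up to 100 kb. In the class up to 1 kb the observed bar stands at 84, and the random means are 0.75 and 2.54.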

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

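No paired analysis was possible because the merged list carries no value per library, and for the same reason no replicate could be left out. The alternatives planned for transcription start sites, annotation classes, motifs, motif spacing and gene lists were not run, since they need an hg19 sequence or annotation. Alternatives for spacing, scores and widths, and those with the span, without ZNF-named genes or without a chromosome, were chosen after seeing the data. The number of chromosomes that differed from their gene share was 3 in the whole list, 1 among peaks scoring above the median, 2 after merging of peaks less than 1 kb apart, and 9 when the expectation came from the span of the peaks instead of from genes. The ratio of chromosome 19 stayed above 1 and past the threshold under each of the 5 alternatives run for it, between 1.51 without chromosome X and 5.51 with the span. The span and the removal of ZNF-named genes (ratio 1.82) raise this ratio by their own construction. Chromosome 19 has many genes for its length and holds 250 ZNF-named genes, so these alternatives cannot test its excess. The ratio of chromosome 13 turned to 0.955 with the span; the alternative's own construction changes the expected number, since chromosome 13 has few genes for its length. Chromosome X kept a ratio below 1 in all 5 alternatives, from 0.392 to 0.577, and missed the threshold only among peaks scoring above the median, which were fewer. The number of chromosomes with shifted scores went from 1 to 0 when peaks less than 1 kb apart were merged; the cause was not tested. Neighbours within 1 kb numbered 112 times the uniform random mean (84 pairs against 0.75). Without chromosome 19 the ratio was 175 (79 pairs against 0.452). That higher ratio came from fewer random pairs, not from more observed pairs. The ratio was 64.4 among peaks scoring above the median (15 pairs). With moves of up to 1 Mb it was 75.3, and with moves of up to 100 kb it was 33.1. Each ratio had the smallest p that 1000 placements allow. Of 23 alternative values with a test, 18 kept direction and side of the threshold, 4 kept direction and missed the threshold, and 1 reversed. The 18 include the span and ZNF alternatives for chromosome 19, which cannot test its excess. The 1 that reversed was chromosome 13 with the span. Depth per library is unknown, so the number of peaks that deeper sequencing would add cannot be stated.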

Other observations

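Tests of peaks scoring above the median, of merged peaks on chromosome 19 and of the ladder share on chromosome 19 were written down before their results were seen. The other tests in this part were chosen after the result was seen. The study has a single merged list and no contrast between conditions, so no explanation by a condition was tested; the ZNF gene explanation is the only biological one tested below.

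The deposited scores were not evenly spread. They took 423 values in 1146 peaks, with 25 peaks at 6.11, 23 at 5.1 and 23 at 5.35. A ladder of equal steps of 0.2508 held 293 peaks (25.6%, within 0.006 of a step), where the best ladder refitted in each of 100 lists with scores moved at random by up to 0.25 held at most 148. Fitted to the 313 peaks with scores above 8 alone, the best ladder again had steps of 0.2508 and held 82 of them (26.2%), against at most 49 in the refitted lists with moved scores. Fitted to scores up to 8 alone, the steps were 0.25. The best-fitting ladder started at an offset of 0.0868. Step and offset were fitted together, and no ladder starting at 0 was fitted. Whether the score is simply proportional to a whole number was therefore not tested. Equal steps are consistent with a score that is linear in a number of reads over a background shared by those peaks, whereas the logarithm of a p-value is not linear in the number of reads. This stays a hypothesis about the column, since the file names no unit and most peaks lie off the ladder.

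The excess of peaks on chromosome 19 did not come from low-scoring peaks alone. Among peaks scoring above the median, 78 were on chromosome 19 against 41.5 predicted from genes (ratio 1.88, interval 1.51 to 2.31). The score has no stated unit, so whether this selection leaves out peaks near the calling threshold is unknown. Counting a region several times did not account for the excess either, since the ratio after merging was 1.61 (interval 1.35 to 1.89). Genes with ZNF symbols, most of which encode zinc finger proteins, number 250 on chromosome 19, and peaks at these genes are a candidate explanation; they would need 25.1 peaks per 100 ZNF genes against 5.52 per 100 genes on the chromosomes other than 7, 16 and 19. Chromosomes 7 and 16, with 65 ZNF genes between them, held 93 peaks (exact Poisson interval 75.1 to 114), where that rate predicts 112 and the rate without it 99, so the count is too small to decide. A local background raised on chromosome 19 also stays open: 27.1% of its peaks had scores on the ladder, against 25.4% elsewhere (p = 0.669, Fisher's exact test), and the copy number of the chromosome in these cells is not analysed here.

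The pairs of peaks within 1 kb were 33.1 times as frequent as in lists with each peak moved by up to 100 kb. Peak density at scales well above 100 kb therefore cannot account for them. Density that varies over shorter distances is removed by the moves, so it stays open. A candidate explanation is that the peak caller divided single enriched regions: the edges of paired peaks lay 54 to 732 bp apart (median 178.5 bp), and in 46.4% of the 84 pairs (exact interval 35.5 to 57.6%) the space between them was no longer than the median peak. The interval includes 50%, and without read profiles divided regions cannot be told apart from neighbouring binding sites.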
